A study of Homo sapiens with 4 samples.

How the data were processed

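RNA was sequenced from 4 samples of SK-N-BE(2) cells, 2 with a scramble hairpin and 2 with a hairpin against TTC8. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the Illumina TruSeq RNA kit, which does not mark the strand. Per the submitters' processing notes, HISAT2 2.2.0 and the genome build hg38 were used. The read counter, its settings and the annotation release are not given in the sources used here. The deposited table holds whole-number counts per Ensembl gene with no normalization by the authors, 1 column per sample, and every column was used. Groups were taken from the sample titles. The hairpin sequence and the number of hairpins are not given in the sources used here, so differences between shTTC8 and shScb cannot be separated from off-target effects of a hairpin.

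The table holds 64252 gene IDs, of which 33779 had a count in any library. Symbols came from a gene name table for 40995 IDs and only from GENCODE 29 (GRCh38, the assembly that hg38 names) for 15596; 7661 had no name. Positions, exons, GC content and transcript lengths were those of GENCODE 29. The counting of reads shared by genes is unknown. Metallothionein, ribosomal protein and histone genes, which have near-identical copies or pseudogenes, are therefore reported as uncertain. For other named genes, shared exonic positions are stated where the overlapping gene had at least 12.4% of the gene's own counts. Named genes with smaller overlaps (at most 7.21%) are not marked.

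Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with default settings (19610), libraries were scaled by TMM, and the quasi-likelihood F test with robust empirical Bayes compared the groups, two-sided, with Benjamini-Hochberg adjustment over all tested genes at 0.05. The fit used edgeR's default prior count. Log2 CPM, used for the gene lists and for correlations between libraries, were computed with a prior count of 2. Standard errors are the log2 fold change over the square root of the quasi-likelihood F statistic. CPM were computed from the TMM-scaled library sizes, and errors on CPM are SDs over 2 libraries. Totals ran from 38284663 to 55331449 counts, and the biological coefficient of variation was 10.5%.

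Before the data were examined, 25 gene lists were fixed, of which 619 of 620 genes matched an ID. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM, adjusted over the lists; camera with an estimated correlation and fry, which tests whether a list's genes move on balance in a shared direction, were alternatives. Counts adjusted over the list alone repeat the Benjamini-Hochberg step within each list. The genes named in the text also followed a rule fixed then: TTC8; the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 5 CPM and no overlap between the groups' libraries; up to 4 called members of each list by smallest p; and a fixed set with MYCN, HAND2, GATA3, ISL1, TH and DBH. Some genes and 1 list that these rules cover are not reported here.

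The tests were tried on simulated data before use. In 19610 genes simulated for the shTTC8 against shScb comparison, 200 were changed. Of these edgeR recovered 10% of the genes changed 1.25-fold, 60% at 1.5-fold, 66% at 2-fold and 92% at 4-fold. It called 0.0876% of unchanged genes. The 200 changed genes were a far smaller share than the 31.9% of genes called in the data. The recovered shares therefore need not hold for this comparison. A simulated raised set of 30 genes was called and 0 of 25 random sets were. Genes were simulated independently of each other, so this does not show how camera behaves for lists of correlated genes.

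Replicates were compared before averaging. Log2 CPM correlated across genes, which are not independent replicates, at r = 0.987 within shScb, 0.986 within shTTC8 and at most 0.974 between groups. A chi-square statistic per degree of freedom of 14.0 in shScb and 7.52 in shTTC8 showed that no pair of replicates was the same library counted again.

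Alternatives were RLE scaling, library size alone, no low-count filter, a stricter filter (at least 1 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, non-robust fitting, the replicate number as a block, each library left out in turn, a minimum of 2-fold and an adjusted p under 0.01. Thinning to equal depth and an offset for GC content and transcript length (lowess span 0.3) were added after seeing the data.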

Results

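Gene expression was measured by RNA sequencing in SK-N-BE(2), an established neuroblastoma cell line that carries amplified MYCN. The cells had received either a scramble short hairpin RNA (shScb) or a hairpin against TTC8 (shTTC8), and each group held 2 libraries. Gene counts summed to 51168727 and 55331449 in shScb replicates 1 and 2. The shTTC8 libraries were shallower, at 38284663 and 40863047 counts. In shScb 1 and 2 and shTTC8 1 and 2, 28298, 28374, 27445 and 27499 genes had a count, respectively. Transcripts of the mitochondrial genome took 8.60% ± 0.476 of the counts in shScb and 7.65% ± 0.0645 in shTTC8 (SD, n = 2).

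The comparison of shTTC8 with shScb asked which transcripts differed when TTC8 was lowered. TTC8 encodes a subunit of the BBSome, the complex that carries membrane proteins in and out of the primary cilium. The gene (ENSG00000165533) is protein coding and lies on the plus strand of chromosome 14, from 88824153 to 88881078 in GRCh38. It had 9888 and 10398 counts in the shScb libraries and 1130 and 1268 counts in the shTTC8 libraries. TTC8 fell from 193 ± 3.05 to 29.9 ± 1.09 CPM (SD, n = 2), with a log2 fold change of -2.70 (SE 0.07, edgeR adjusted p = 5.38e-12), so that 0.154 of the shScb level remained. In the same libraries MYCN, the amplified oncogene of this line, fell from 5738 ± 109 to 3766 ± 75.4 CPM (SD, n = 2). The intermediate filament gene VIM fell from 2481 ± 16.1 to 1349 ± 49.5 CPM (SD, n = 2). As groups, mesenchymal state genes, extracellular matrix genes and mitotic genes were lower in shTTC8, and neuronal differentiation genes and nuclear oxidative phosphorylation genes were higher (camera, preset correlation). Those group calls were lost by camera with an estimated correlation (adjusted p = 0.529 for each of them). That test has 2 residual degrees of freedom here, and so little power to call a list. Except for neuronal differentiation genes (-0.0239), its estimated correlations for these groups also lay above the preset 0.01, at 0.0626 to 0.178.

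Of 19610 genes that passed the low-count filter, edgeR's quasi-likelihood test called 2974 higher and 3284 lower in shTTC8, together 31.9% of the genes tested. Most of these changes were small, with a median absolute log2 fold change of 0.47 among called genes. By at least 2-fold, 468 genes were higher and 570 lower. Among protein-coding genes 39.2% were called, against 12.1% among other gene types. In 65.5% of tested genes both shTTC8 libraries lay on the same side of both shScb libraries, where chance gives 33.3%. Changes of single genes and medians of gene lists are log2 fold changes of shTTC8 over shScb, and the members of a list counted as higher or lower passed edgeR's threshold. Without shTTC8 replicate 1, 1880 genes were higher and 2383 were lower. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

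**Figure D1:**
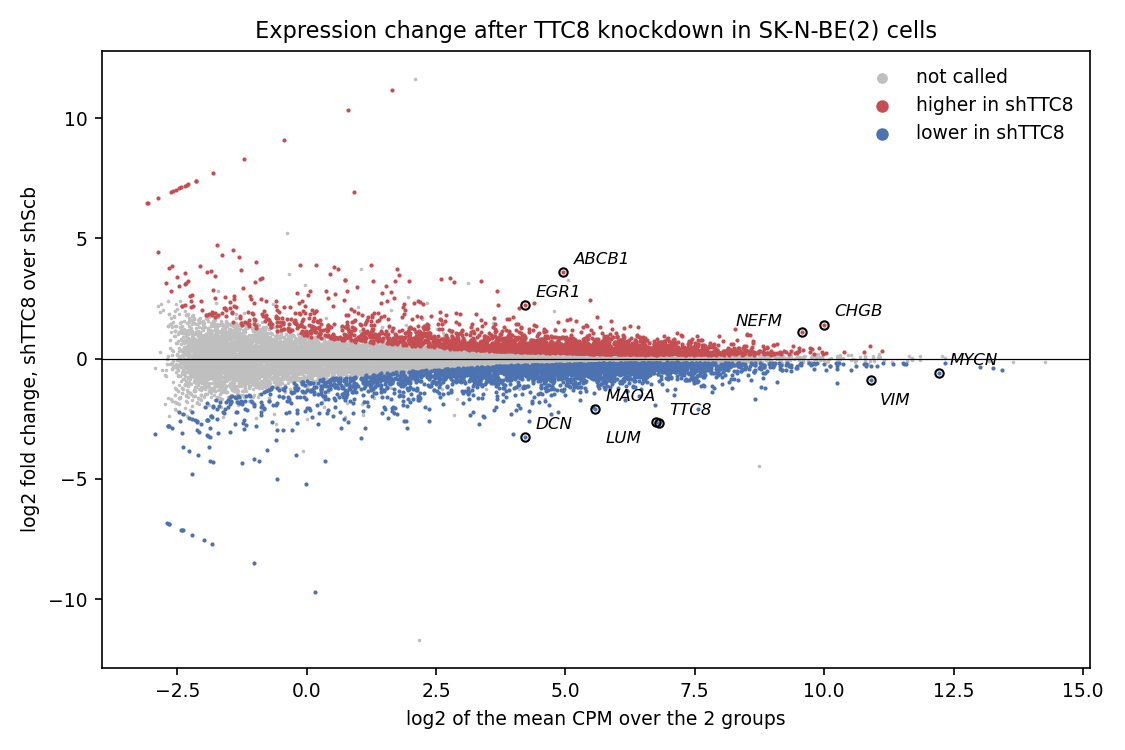
Log2 fold change of shTTC8 over shScb (y axis) against the log2 mean CPM (x axis) for the 19610 tested genes, with the 2974 higher genes in red, the 3284 lower genes in blue and the others in grey. Circled genes are named in the text. Of the 32 genes beyond a log2 fold change of 6 in either direction, 31 had no count in a whole group. The fitted values of these 31 depend on edgeR's default prior count.

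Among called genes with a symbol, a mean of at least 5 CPM and no overlap between the groups' libraries, the largest rise was that of ABCB1. It encodes the multidrug efflux pump P-glycoprotein. ABCB1 (ENSG00000085563, chromosome 7, 87503633 to 87713323, GRCh38) rose from 4.77 ± 0.200 to 57.2 ± 0.0880 CPM (SD, n = 2; log2 fold change 3.58, SE 0.10, edgeR adjusted p = 6.67e-12). KCNK2, a background potassium channel, rose 9.99-fold to 10.9 CPM. The zinc finger gene ZNF467 rose from 1.42 ± 0.695 to 13.0 ± 0.304 CPM (SD, n = 2). Its log2 fold change of 3.19 (SE 0.31) was 3.80 without shScb replicate 2 and 2.76 without shScb replicate 1. The sulfotransferase gene CHST8 rose 6.93-fold to 22.4 CPM. SERTM2, NELL1, EGR1 and SCRT2 rose 5.48-, 4.94-, 4.70- and 4.67-fold. The rises of MT1F (10.3-fold) and TMEM200B (9.33-fold) are uncertain. MT1F has near-identical metallothionein paralogs, and TMEM200B shares exonic positions with a gene whose counts were 1419% of its own.

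The largest falls among such genes included a pair of neighbouring genes for secreted proteoglycans. DCN (ENSG00000011465, chromosome 12, 91140484 to 91183123, GRCh38), which encodes decorin, fell from 33.8 ± 0.166 to 3.50 ± 0.248 CPM (SD, n = 2; log2 fold change -3.27, SE 0.11, edgeR adjusted p = 1.03e-10). LUM (ENSG00000139329, chromosome 12, 91102629 to 91111831, GRCh38), which encodes lumican, fell from 185 ± 7.65 to 29.9 ± 1.83 CPM (SD, n = 2; log2 fold change -2.63, SE 0.07, edgeR adjusted p = 6.67e-12). ADAMTS2, a procollagen-processing protease, changed by -3.12 on the log2 scale (SE 0.13), and ANGPT1, the angiopoietin ligand of TEK, by -2.58 (SE 0.13). RAB27B, a GTPase of secretory vesicles, CLSTN2, DAND5 and PKHD1, which encodes the ciliary protein fibrocystin, fell to 0.168, 0.184, 0.191 and 0.198 of their shScb levels.

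Of the 13 tested genes of the BBSome list, which holds BBSome subunits other than TTC8 with their chaperonins and partners, 6 were lower and none was higher (7 lower and 1 higher adjusted over the list alone). Their median log2 fold change was -0.32. LZTFL1, a regulator of BBSome entry into cilia, changed by -0.81 (SE 0.14) and the subunit BBS7 by -0.48 (SE 0.10). The centrosomal gene CEP290 changed by -0.67 (SE 0.09), but shares exonic positions with a gene that had 120% of its counts. As a group the list did not pass (camera adjusted p = 0.103). Among 25 intraflagellar transport genes, 5 were higher and 1 was lower, the same numbers adjusted over the list alone. The group did not pass either (median 0.06, camera adjusted p = 0.462). The kinesin subunit gene KIF3B rose by 0.71 (SE 0.07) and IFT27 by 0.41 (SE 0.08) on the log2 scale. The lower gene, IFT80, had the smallest p of the list and changed by -0.85 (SE 0.09), but shares exonic positions with a gene that had 536% of its counts. Hedgehog and Wnt targets were lower as a group (median -0.33, camera adjusted p = 0.0372). The call was lost in other settings (adjusted p = 0.529 with an estimated correlation, 0.0619 with a stricter low-count filter, 0.115 without shScb replicate 2 and 0.0536 without shTTC8 replicate 2). Of 19 tested, 7 were lower and 1 higher (8 lower and 3 higher adjusted over the list alone). ZNRF3, a Wnt-induced ubiquitin ligase that removes Wnt receptors, fell from 47.7 ± 0.559 to 10.3 ± 0.857 CPM (SD, n = 2; log2 fold change -2.20). The receptor gene FZD7 changed by -0.93 and LGR5 by -0.70, while the Hedgehog co-receptor gene BOC rose by 0.43.

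Among 19 adrenergic core regulators, the transcription factors that define the sympathetic identity of neuroblastoma cells, 11 were lower and 3 higher (12 lower and 3 higher adjusted over the list alone). Their median was -0.36. The group was lower by camera with its preset correlation (adjusted p = 0.0322), but lost its call in other settings (adjusted p = 0.538 with an estimated correlation, 0.0901 without shScb replicate 2 and 0.0869 without shTTC8 replicate 1). Within it MYCN changed by -0.61 (SE 0.06, edgeR adjusted p = 3.49e-06), KLF7 by -0.65 (SE 0.07) and GATA3 by -0.49 (SE 0.06). ISL1 rose by 0.27 (SE 0.06, edgeR adjusted p = 0.0033), a call that was lost without shTTC8 replicate 2 (edgeR adjusted p = 0.0701). HAND2 stood at 948 ± 58.3 CPM in shScb and 988 ± 42.9 CPM in shTTC8 (SD, n = 2) and was not called (log2 fold change 0.06, SE 0.07, edgeR adjusted p = 0.531). It shares exonic positions with its antisense gene, which had 49.3% of its counts.

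Genes for catecholamine synthesis and storage moved in both directions, with 10 of 18 higher and 7 lower (11 higher and 7 lower adjusted over the list alone). Their median was 0.39 (camera adjusted p = 0.337). Among the lower genes were enzymes of noradrenaline synthesis, TH at -0.36 (SE 0.06) and DBH at -0.80 (SE 0.06), and MAOA, which degrades monoamines, at -2.11 (SE 0.08). The storage granule protein gene CHGB rose from 554 ± 16.4 to 1478 ± 9.35 CPM (SD, n = 2; log2 fold change 1.41, SE 0.06, edgeR adjusted p = 1.11e-09). PCSK1N rose by 1.07 (SE 0.07), and SLC6A2, the noradrenaline transporter, rose by 0.94 (SE 0.06). SLC6A2 shares exonic positions with a gene that had 28.6% of its counts. Of 27 tested neuronal differentiation genes, 16 were higher and 3 lower, the same numbers adjusted over the list alone. Their median was 0.46 (camera adjusted p = 0.0021; adjusted p = 0.529 with an estimated correlation). The neurofilament gene NEFM rose from 485 ± 0.548 to 1039 ± 21.2 CPM (SD, n = 2; log2 fold change 1.10, SE 0.06). SNAP25, of the synaptic vesicle fusion machinery, rose by 1.37 (SE 0.07) and the microtubule-associated DCX by 0.98 (SE 0.06), while the receptor tyrosine kinase gene RET changed by -0.95 (SE 0.06).

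**Figure D2:**
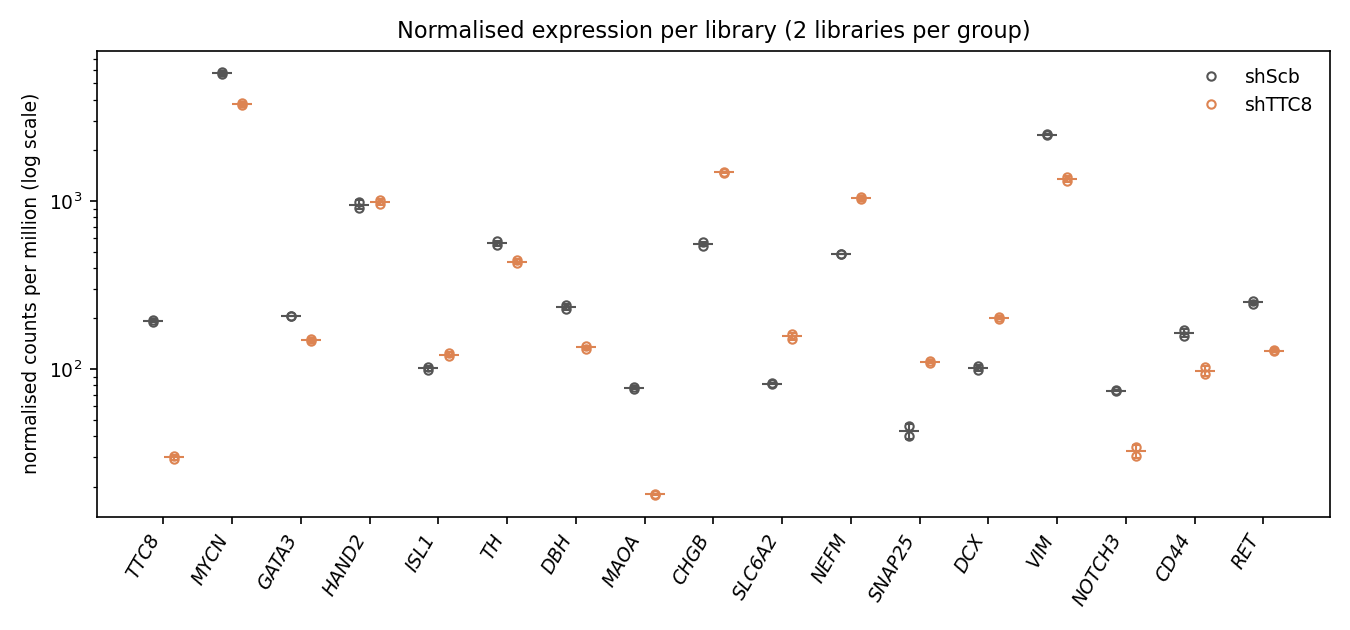
Normalised CPM (y axis, log scale) of genes named in the text (x axis) in each library, with shScb in grey and shTTC8 in orange; circles are the 2 libraries of a group, and bars give the mean ± SD. TTC8, MYCN and VIM lie lower in both shTTC8 libraries, CHGB and NEFM lie higher, and HAND2 (948 against 988 CPM) was not called.

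The mesenchymal state list held 22 genes. Its untested members, named here outside the naming rule, did not pass the low-count filter: PRRX1, RUNX2, TBX18, MEOX1, MEOX2, TWIST2 and YAP1. Of the 15 tested genes, 12 were lower and none higher, the same numbers adjusted over the list alone. Their median was -0.88 (camera adjusted p = 3.65e-06; adjusted p = 0.529 with an estimated correlation). Besides VIM (log2 fold change -0.88, SE 0.06), the receptor gene NOTCH3 changed by -1.19 (SE 0.08), the AP-1 subunit gene FOSL2 by -0.98 (SE 0.07) and the hyaluronan receptor gene CD44 by -0.75 (SE 0.07). Extracellular matrix and epithelial-mesenchymal transition genes were lower in 20 and higher in 3 of 32 cases (21 lower and 3 higher adjusted over the list alone). Their median was -0.43 (camera adjusted p = 2.66e-04; adjusted p = 0.529 with an estimated correlation). The collagen gene COL6A2 changed by -1.16 (SE 0.08), the metalloproteinase inhibitor gene TIMP3 by -1.75 (SE 0.13) and the cadherin gene CDH11 by -0.90 (SE 0.09). Markers of fibroblasts and endothelium, cell types that a pure culture of the line would not hold, moved with these groups. The lists are not independent. COL1A1 and COL3A1 are also in the extracellular matrix list, which shares a further member with the mesenchymal state list. Of 10 tested fibroblast and endothelial markers, 7 were lower and 2 higher, the same numbers adjusted over the list alone. Their median was -0.41 (camera adjusted p = 0.0183; adjusted p = 0.529 with an estimated correlation, and 0.0782 without shScb replicate 1). The lower ones included DCN and LUM, as well as COL1A1 (log2 fold change -2.07, SE 0.22) and VWF, at 1.21 ± 0.278 CPM in shScb and 0.113 ± 0.0227 CPM in shTTC8 (SD, n = 2). Of 7 tested Schwann cell and glia markers, 2 were lower and none higher, the same numbers adjusted over the list alone. Their median was -0.21 (camera adjusted p = 0.477), and the neurotrophin receptor gene NGFR changed by -1.86 (SE 0.10). Of 6 tested epithelial and blood cell markers, 2 were lower and none higher (2 lower and 1 higher adjusted over the list alone). Their median was -0.43 (camera adjusted p = 0.252). The leukocyte phosphatase gene PTPRC stood at 15.4 ± 0.520 CPM in shScb and 3.27 ± 0.394 CPM in shTTC8, and KRT19 at 1.46 ± 0.0614 and 0.483 ± 0.137 CPM (SD, n = 2).

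**Figure D3:**
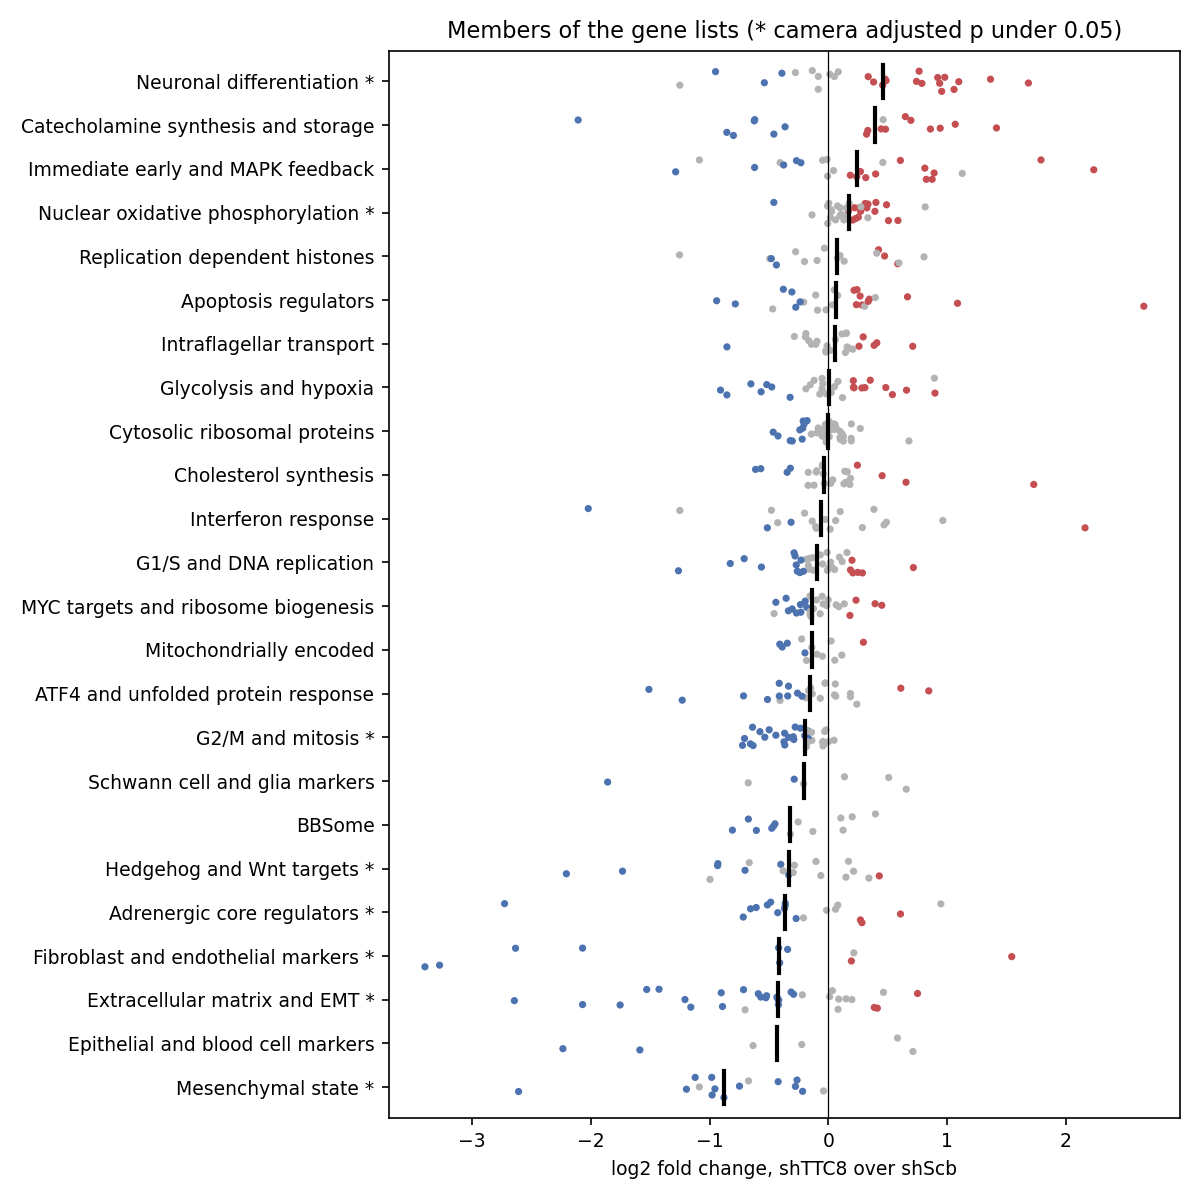
Log2 fold change of shTTC8 over shScb (x axis) for each tested member of the gene lists described in the text (y axis), in red or blue where edgeR called the gene higher or lower and grey otherwise; black bars are list medians and asterisks mark a camera adjusted p under 0.05. Medians run from -0.88 for the mesenchymal state to 0.46 for neuronal differentiation, and no asterisk is kept with an estimated correlation.

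Mitotic genes were lower. In the list, 21 of 35 G2/M genes fell and none rose (26 lower and none higher adjusted over the list alone). Their median was -0.20 (camera adjusted p = 1.67e-05; adjusted p = 0.529 with an estimated correlation). The mitotic kinase gene CDK1 fell from 144 ± 7.73 to 88.0 ± 2.46 CPM (SD, n = 2; log2 fold change -0.71, SE 0.06, edgeR adjusted p = 1.06e-06), and the kinetochore genes CENPE and CENPF changed by -0.72 (SE 0.07) and -0.53 (SE 0.06). G1/S and DNA replication genes went both ways, with 11 of 34 lower and 6 higher (12 lower and 6 higher adjusted over the list alone). Their median was -0.10 (camera adjusted p = 0.232). The replication licensing gene CDT1 changed by -0.83 (SE 0.08) and GINS4 by -0.71 (SE 0.08), and CCNE1, cyclin E1, rose by 0.72 (SE 0.10). Of 28 MYC targets and ribosome biogenesis genes 9 were lower and 4 higher (12 lower and 4 higher adjusted over the list alone). Their median was -0.14 (camera adjusted p = 0.191). The polyamine synthesis gene ODC1, a direct MYC target, rose by 0.45 (SE 0.06). The nucleolar GTPase gene GNL3 changed by -0.44 (SE 0.06) and the ribosome biogenesis gene WDR12 by -0.36 (SE 0.06); both share exonic positions with genes that had 26.3% and 12.4% of their counts.

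Of 26 apoptosis regulators 10 were higher and 6 lower (11 higher and 6 lower adjusted over the list alone). Their median was 0.06 (camera adjusted p = 0.578). The anti-apoptotic gene BCL2 fell from 77.6 ± 0.111 to 40.4 ± 0.702 CPM (SD, n = 2; log2 fold change -0.94, SE 0.07), and BMF changed by -0.78 (SE 0.10). The pro-apoptotic gene BAX rose by 0.67 (SE 0.08) and CYCS, cytochrome c, by 0.34 (SE 0.06).

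Nuclear-encoded oxidative phosphorylation genes were higher in 15 and lower in 1 of 35 cases (18 higher and 1 lower adjusted over the list alone). Their median was 0.18 (camera adjusted p = 0.0018; adjusted p = 0.529 with an estimated correlation). The complex I subunit gene NDUFA8 rose by 0.51 (SE 0.07) and the complex IV subunit gene COX5A changed by -0.46 (SE 0.06). Of the 13 genes encoded by the mitochondrial genome, 4 were lower and 1 higher (5 lower and 1 higher adjusted over the list alone). Their median was -0.14 (camera adjusted p = 0.252), and MT-CO2 changed by -0.35 (SE 0.06). Glycolysis and hypoxia genes split into 10 higher and 7 lower of 30, the same numbers adjusted over the list alone. Their median was 0.003 (camera adjusted p = 0.75). The glycolytic enzyme gene PGAM1 rose by 0.66 (SE 0.06), whereas the hypoxia-induced genes P4HA1, ADM and VEGFA changed by -0.91, -0.85 and -0.65. Cholesterol synthesis genes were higher in 4 and lower in 4 of 25 cases (4 higher and 5 lower adjusted over the list alone). Their median was -0.03 and their mean 0.06. The direction by camera was up (adjusted p = 0.995) and that by fry was down. INSIG1, which holds back the sterol sensor, changed by -0.61 (SE 0.06). Among 26 genes of ATF4 and the unfolded protein response, 10 were lower and 2 higher (10 lower and 4 higher adjusted over the list alone). Their median was -0.16 (camera adjusted p = 0.0879). The lower ones included the serine synthesis gene PSAT1, which fell from 204 ± 6.45 to 71.5 ± 3.22 CPM (SD, n = 2; log2 fold change -1.51, SE 0.06), SHMT2 at -0.71 (SE 0.06) and the cystine transporter gene SLC7A11 at -1.23 (SE 0.13), while SESN2 rose by 0.84 (SE 0.11).

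Immediate early and MAPK feedback genes were higher in 12 and lower in 5 of 25 cases (13 higher and 5 lower adjusted over the list alone). Their median was 0.24 (camera adjusted p = 0.0919). EGR1, an immediate early transcription factor, rose from 6.52 ± 0.272 to 30.7 ± 1.98 CPM (SD, n = 2; log2 fold change 2.23, SE 0.10, edgeR adjusted p = 2.55e-09), and the phosphatase genes DUSP6 and DUSP1 rose by 0.81 (SE 0.06) and 0.82 (SE 0.10). Interferon response genes gave 3 lower and 1 higher of 20 tested, the same numbers adjusted over the list alone. Their median was -0.06 (camera adjusted p = 0.641), and OAS1 stood at 5.11 ± 0.790 CPM in shScb and 1.26 ± 0.102 CPM in shTTC8 (SD, n = 2). Of 40 cytosolic ribosomal protein genes 10 were lower and none higher, the same numbers adjusted over the list alone (median -0.005, camera adjusted p = 0.578). Of 17 tested replication-dependent histone genes 3 were higher and 2 lower, the same numbers adjusted over the list alone. Their median was 0.08 (camera adjusted p = 0.829). Counts of both families are uncertain, since their members have near-identical copies or pseudogenes. RPS7 changed by -0.46 (SE 0.07) and the histone gene H2BC5 rose by 0.58 (SE 0.13).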

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

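Thinning to equal depth and the offset for GC content and transcript length were chosen after the data were seen. TTC8 was called lower in every setting. Counts of calls stayed within 1.5 times those reported under both other scalings, both other filters, DESeq2, limma-voom, non-robust fitting, thinning and the offset, and no gene called in both the reported and another setting changed sign. Leaving out a library gave 1880 to 3395 higher and 2383 to 3555 lower genes; the 1880 came without shTTC8 replicate 1, and with 1 library left in a group that library is assumed to vary like the other group. A minimum of 2-fold left 468 higher and 570 lower genes, and an adjusted p under 0.01 left 1917 higher, by construction. The replicate numbers did not pair the libraries (correlation of same-numbered deviations 0.0317, over 2 pairs only); with the replicate block 3092 genes were higher and 3343 lower, the adrenergic list was no longer called (adjusted p = 0.0537), and no other call of a list or named gene changed. Camera with an estimated correlation, which has 2 residual degrees of freedom here, called 0 lists higher and 0 lower instead of 3 and 6. Fry called 4 higher and 11 lower. A call lost with so few degrees of freedom says little about a list. For neuronal differentiation genes the estimated correlation, -0.0239, was below the preset 0.01, so a higher correlation did not cost that call. For the other called lists described here it was above the preset. It ran from 0.0626 for extracellular matrix genes to 0.281 for fibroblast and endothelial markers. For these lists a higher correlation and the few degrees of freedom cannot be told apart. Otherwise the cause of these differences was not tested. Over all settings 10 of the 115 genes besides TTC8 under the naming rule and 16 of the 25 lists changed their call in at least 1 setting, none of these with a reversed direction. ATF4 genes were called lower without a filter (camera adjusted p = 0.0401) and with the offset (0.0324), and MYC targets with the offset (0.0222). Counts within some lists moved further with the offset. The BBSome list then had 3 higher and 6 lower genes, and intraflagellar transport genes 9 higher and 1 lower. MYC targets and ribosome biogenesis genes had 4 higher and 16 lower. Of simulated changes edgeR recovered 60% at 1.5-fold and 92% at 4-fold. Recovery was not split by expression level, and far fewer genes were changed in the simulation than were called in the data.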

Other observations

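The tests of gene families by symbol, the search for genes present in only some libraries, and the thinning were chosen after the results they bear on were seen. So were the offset for GC content and transcript length, its use on chromosome windows, and the tests on the fall of DCN and LUM.

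Among 255 families of at least 8 tested genes that share a symbol stem, 2 passed camera with its preset correlation. Genes with the stem NDUFA were higher in 12 of 14 cases and lower in none (median log2 fold change 0.28, camera adjusted p = 0.0408). Collagen genes (COL) were lower in 12 and higher in 2 of 26 cases (median -0.57, camera adjusted p = 0.0408). Neither call was kept by camera with an estimated correlation (adjusted p = 0.975 for both), which has little power here. Both families share members with the oxidative phosphorylation and extracellular matrix lists.

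In 17 genes a library had no count while the other library of its group had at least 100. Chosen after their values were seen, BIVM-ERCC5 had 303 and 2304 counts in shScb and 1963 and 0 in shTTC8, and CORO7-PAM16 had 893 and 0 in shScb and 1 and 0 in shTTC8. All 13 of these genes with a GENCODE 29 position share exonic positions with another gene, against 48.6% of tested genes.

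The number of genes called, 6258, is large for 2 libraries against 2. Lower depth of the shTTC8 libraries is argued against by thinning all 4 libraries to the smallest total, which left 6218 calls. GC content and transcript length as the source of the number are argued against by the offset, with which 6707 genes were called. Single calls did depend on it, since 86.7% of the 6258 were kept with the offset. Without it, log2 fold changes rose with GC content (Spearman's rho 0.210 across genes, which are not independent). The 3 splits of the 4 libraries into 2 and 2 are too few to reach a share under 0.05. The real split called 6258 genes, and only this 1 of the 3 splits gave as many. The highest of the others called 0 (edgeR). Each of the others put 1 library of each group on both sides, so a difference between the groups would itself lower their calls. A difference between the cultures other than TTC8, or an off-target effect of a hairpin, falls together with the groups and was not tested.

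DCN and LUM, which are abundant in fibroblasts, fell together. Fibroblasts lost from the shTTC8 cultures would also take away their collagen I and III transcripts, but COL1A1, COL1A2 and COL3A1 together lost 7.23 CPM on average (6.40 to 8.06 over pairs of libraries; CPM of the total counts here, without TMM scaling), against 182 CPM (175 to 189) for DCN and LUM, and COL1A2 had 7 and 5 counts in shScb. Of the 16 fibroblast and endothelial markers 10 were high enough to be tested. A change of the whole region is argued against by the other 45 tested genes within 5 Mb of DCN, with a median log2 fold change of -0.0473 (SD 0.509), 8 lower and 6 higher. A lower level of both genes within the neuroblastoma cells themselves may account for the fall, as a hypothesis found in these data and not tested.

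Genes of a region of chromosome 1 were shifted together. The window of 50 neighbouring genes from 32936445 to 37947057 (GRCh38) had a median log2 fold change of 0.29, with 25 genes called higher and 2 lower. Windows on chromosome 7 (median -0.273) and chromosome 19 (median 0.265) also lay beyond the 95th percentile of shuffles given below. For a copy number difference between the cultures the test cannot decide: the value of 0.2948 lay above the 95th percentile of 1000 shuffles of gene order (0.256) but below the highest (0.312), and the bound written beforehand, the full range of the shuffles, was too loose, since only 2 of 1000 shuffles reached the observed value. Window medians followed window GC content (Spearman's rho 0.744 across overlapping windows, which are not independent). With GC and length trends removed, the largest median was still that of the chromosome 1 window. It was 0.313, above the highest of 1000 shuffles (0.288). The largest outside chromosome 1 was then 0.200, on chromosome 19, below the 95th percentile of those shuffles (0.235). A copy number difference could account for the chromosome 1 region, as could neighbouring genes that respond together. No DNA measurement was analysed here.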
